A study of Mus musculus with 2 samples.

How the data were processed

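Genomic DNA from colonic mucosa of C57BL/6 mice at postnatal day 90 (P90) and postnatal day 30 (P30) was compared on 2 arrays of a methylation specific amplification microarray (MSAM). In this type of assay, the methylation-sensitive enzyme SmaI and amplification of the digested DNA are used to read the methylation of genomic intervals that lie between SmaI sites. In the usual form of the method, an interval is amplified when the sites at its ends are methylated, so a higher signal stands for more methylation there. Per the labels, the P30 DNA carried Cy3 and the P90 DNA carried Cy5 on both arrays. There were 0 arrays with the dyes swapped, so the age comparison and the dye comparison are one and the same in these data. The titles pair a P90 and a P30 sample by a letter (90b with 30b, and 90e with 30e), and the arrays were numbered 1 and 2 in that order. The study design calls the 2 comparisons independent. The labels do not say how many animals contributed to a DNA sample, so the spread between the arrays is the only replicate error.

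The series' own description of the array states 90535 probes covering 77% of the 31019 SmaI intervals from 200 bp to 2 kb long, at an average of 3.8 probes per interval. Probes of one interval measure one amplified fragment and are therefore not independent. The arrays were read with Agilent Feature Extraction 8.5.1.1, per the submitters' processing notes. The background correction, the dye normalization, the filters and the genome build are not given in the sources used here.

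The authors deposited 1 processed value per feature (a spot on the array) and array, and these values were read as log10 ratios of Cy5 over Cy3, hence of P90 over P30. The direction follows from the dyes in the labels and the order of the ages in the titles, and the base of 10 from the form in which this software writes its log ratio. Neither is stated with the values, so direction and scale are likely rather than known. Fold changes and log2 values depend on that base, while the moderated test does not. The values ran from -0.907 to 0.825 on replicate 1 and from -0.840 to 0.850 on replicate 2. The median over all features was 0 on both arrays. No scanner file with channel intensities was used, so brightness, background and saturation are unknown here.

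The table held 96645 features, numbered up to 105072. The other 8427 numbers in that range were not analysed here. The features carry numbers only. No annotation of the features was used here, so no gene, chromosome or interval is named. The comparisons planned per interval, per gene, per gene list and per chromosome were therefore not made. At most 2 feature numbers per direction are printed, by a rule fixed before the data were examined: those with the largest and smallest mean ratio among features past the test with the same direction on both arrays.

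A value of exactly 0 on both arrays was found for 6503 features (6.73%). These were left out of the test, because identical values have no spread between the arrays from which the test could learn. What an exact 0 codes for is not stated in the sources used here, so whether they hold measured ratios is not known. That choice was made after the zeros were seen and before any test was run. A further 797 features were exactly 0 on replicate 1 only and 1224 on replicate 2 only, and these were kept at 0. This left 90142 features. Their log ratios were multiplied to the log2 scale, and each array was centred on its median, which was -0.021 on replicate 1 and -0.0076 on replicate 2 before centring (log2). No loess or quantile step was applied.

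Each feature's mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, then eBayes, two-sided), with Benjamini-Hochberg adjustment at 0.05. With 2 arrays a feature has 1 residual degree of freedom, and the moderated test borrowed 3.23 prior degrees of freedom from all features. Agreement between the arrays was measured by correlations across features, which are not independent replicates, and by counts of features at or beyond 1.5-fold on both arrays in the same or in opposite directions. The number of arrays limits the precision of every value.

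The test was tried on simulated data for this comparison with 90142 features and the spread of the real fit. With 200 changed features, it called 0% of the 50 features changed 1.5-fold, 6% of those changed 2-fold, 70% of those changed 3-fold and 98% of those changed 4-fold, and 7 of its 94 calls were unchanged features. With 27043 changed features whose effects gave, over all features, the covariance of the real arrays, it called 43.4% of them. Of its 12179 calls, 3.60% were unchanged features. The simulated noise followed the model that the test assumes, with independent features, no exact zeros and no dye effect. These shares therefore do not measure the error among the real calls. The shares by fold also hold only for 200 changed features, because the cutoff of the adjustment depends on how many features change. The alternatives tried were the ratios as deposited, a common scale for the arrays, the test without eBayes, robust eBayes, a looser adjusted p, fold rules without a test, other treatments of the zeros, removal of local medians by position, and other log bases.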

Results

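The study asked how DNA methylation in the mouse colonic mucosa differs between P90, a young adult age, and P30, shortly after weaning. It comprised 2 arrays with a pair of dyes each, each setting 1 P90 DNA sample against 1 P30 DNA sample, and 90142 features entered the comparison. A feature is a spot that reports on a SmaI interval or is one of the array's other spots, and these kinds were not told apart here.

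Most features lay close to the array's median ratio. A shift common to all features would be removed by the centring, or by any dye normalization before it, and cannot be seen here. On replicate 1, 88.6% of features lay within 1.5-fold of the array's median ratio, and on replicate 2 the share was 90.5%. The central 90% of log2(P90/P30) ran from -0.60 to 0.63 on replicate 1 and from -0.56 to 0.58 on replicate 2. Beyond 1.5-fold, replicate 1 had 5498 features higher at P90 and 4742 lower, and replicate 2 had 4501 higher and 4071 lower.

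The differences that were present repeated in part between the 2 independent comparisons. Of 10240 features at or beyond 1.5-fold on replicate 1 and 8572 on replicate 2, 4479 were so on both in the same direction. Across features, the arrays' ratios correlated with Pearson's r = 0.700 and Spearman's rho = 0.721, and 78.0% of features had the same direction on both. The SD of the component shared by the arrays was 0.31 on the log2 scale, a 1.24-fold difference, against an SD of 0.21 for the part specific to an array. The shared differences were thus larger, as an SD, than the spread between the 2 comparisons. Because the dyes were never swapped, the shared component holds any feature-specific difference between Cy5 and Cy3 as well as the difference between the ages.

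A total of 4479 features (4.97%) were at or beyond 1.5-fold in the same direction on both arrays. Of these, 2620 were higher at P90 and 1859 were lower. If the arrays had been independent, 275 higher and 214 lower features would have been counted by chance. Only 126 features passed 1.5-fold on both arrays in opposite directions. At 2-fold, 411 features were higher on both arrays, 199 were lower on both and 16 were in opposite directions. At 3-fold, 49 were higher on both, 7 were lower on both and 2 were in opposite directions. Higher features made up 58.5% of the same-direction features at 1.5-fold, 67.4% at 2-fold and 87.5% at 3-fold. The direction of the deposited ratio is likely but not stated with the values. If it were P30 over P90, higher and lower would be exchanged, with 1859 features higher and 2620 lower at 1.5-fold, and higher features would make up 41.5%, 32.6% and 12.5% at the same thresholds. The counts also rest on the reading of the values as base 10, and would be 11 at 1.5-fold if they were base 2.

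**Figure D1:**
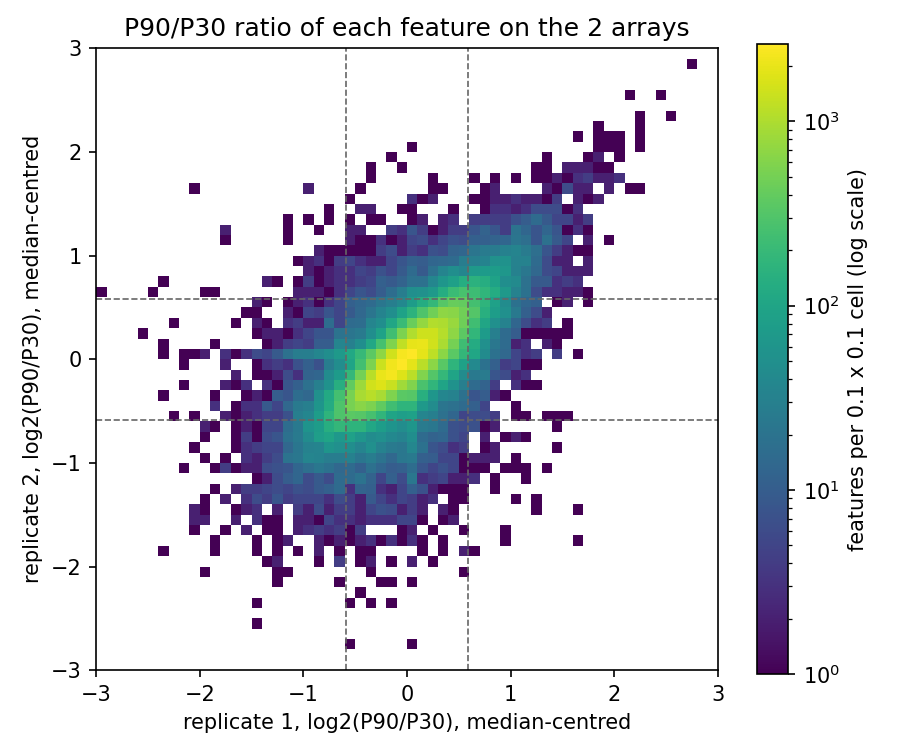
Each cell gives the number of features (colour, log scale) at a log2(P90/P30) ratio on replicate 1 (horizontal axis) and on replicate 2 (vertical axis), both centred on the array's median, with dashed lines at 1.5-fold. The cloud follows the diagonal (Pearson's r = 0.700), with a narrow upper right tail in which 49 features were at least 3-fold higher at P90 on both arrays, against 7 in the lower left that were at least 3-fold lower on both.

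Large increases and large decreases of the ratio repeated to different degrees. Of the 940 features at least 2-fold higher at P90 on replicate 1, 79.7% were at least 1.5-fold higher on replicate 2, against 55.5% of the 802 features at least 2-fold lower (Fisher's exact test, two-sided, p = 1.8e-27). With the arrays' roles exchanged, 77.7% of 815 increases and 48.8% of 880 decreases repeated (Fisher's exact test, two-sided, p = 1.9e-35). Several features can report on one interval, so these p-values are too small. Both readings use the same arrays and share features, so they are not independent of each other. This comparison was chosen after the values that show it were seen. With the ratio read as P30 over P90, the better repeated features would be those lower at P90. The 92 features at least 3-fold higher on replicate 1 had a median ratio of 3.07-fold on replicate 2, and 97.8% of them were higher there. The 86 features at least 3-fold lower on replicate 1 had a median of 0.67 times the P30 signal on replicate 2, and 72.1% of them were lower there. Features chosen on replicate 2 gave a median of 3.13-fold on replicate 1 for the 87 that were at least 3-fold higher and of 0.66 for the 113 that were at least 3-fold lower, with the same direction in 90.8% and 79.6% of them. Among the features at least 3-fold lower, 8 of the 86 and 6 of the 113 were exactly 0 on the array they were read on, against 1 of the 92 and 1 of the 87 at least 3-fold higher, and after centring such a feature counts as slightly higher. Without the features at 0 on either array, an alternative chosen after the data were seen, the shares with the same direction were 97.8% of the higher and 79.2% of the lower features read on replicate 2, and 90.8% and 83.8% read on replicate 1. The medians without them were 3.09-fold and 0.64 on replicate 2 and 3.14-fold and 0.65 on replicate 1.

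**Figure D2:**
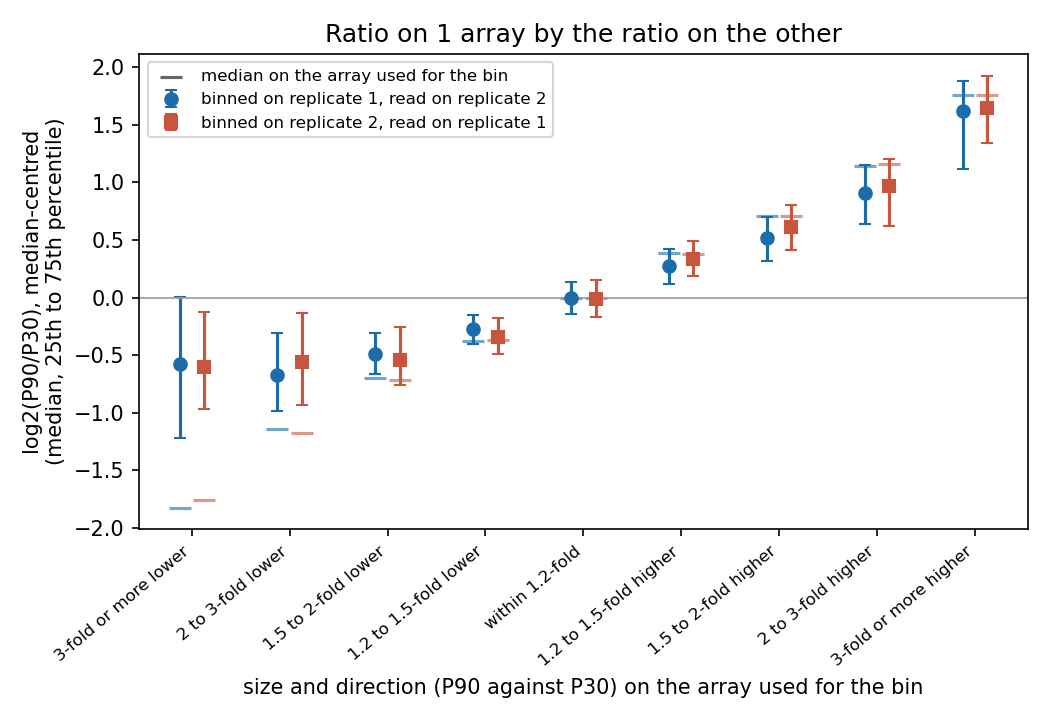
Features were binned by the size and direction of their P90 against P30 difference on 1 array (horizontal axis), and their centred log2(P90/P30) on the other array is shown as the median with the interquartile range (points and bars), beside the median on the array used for the bin (short lines). For features at least 3-fold higher on replicate 1, the median on replicate 2 was 1.62, near the 1.76 of the selecting array, while for features at least 3-fold lower it was -0.58 against -1.82, with 8 of these 86 features at exactly 0 on replicate 2 (-0.65 against -1.82 without zeros).

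The moderated test called 15325 of the 90142 features (17.0%) at an adjusted p of 0.05, 8209 higher and 7116 lower at P90. With 2 arrays and the 3.23 prior degrees of freedom estimated here, only a feature with the same direction on both can pass this test. With the ratios as deposited, without centring, it called 8677 higher and 8859 lower, so which direction held more features turned with the centring. The median size of a called difference was 1.47-fold, the smallest was 1.29-fold, and 8753 called features had a mean difference under 1.5-fold. A mean of at least 2-fold was reached by 633 called features that were higher and 386 that were lower. With the ratio read as P30 over P90, 7116 called features would be higher and 8209 lower, and 386 higher and 633 lower at 2-fold. The smallest adjusted p was 0.029 (limma, Benjamini-Hochberg). The count depends on how the spread was modelled: with the 6503 features at 0 on both arrays kept in the fit, limma called 0 features, with 32002 at an unadjusted p under 0.05. The test without moderation also called 0, with 13214 at an unadjusted p under 0.05.

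The largest mean increase belonged to feature 6041, at log2 2.80 ± 0.05 (SD, n = 2), or 6.95-fold higher at P90, with an adjusted p of 0.029 by limma. Feature 77078 followed at log2 2.49 ± 0.08 (SD, n = 2), or 5.61-fold higher. The largest mean decrease belonged to feature 41752, at log2 -2.08 ± 0.34 (SD, n = 2), or 4.24-fold lower at P90, with an adjusted p of 0.029 by limma. Feature 3608 had log2 -1.999 ± 0.82 (SD, n = 2), with -1.42 on replicate 1 and -2.58 on replicate 2, and an adjusted p of 0.033 by limma. With the ratio read as P30 over P90, features 6041 and 77078 would be the largest decreases and features 41752 and 3608 the largest increases.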

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

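Of the alternatives below, the removal of position, the log bases and the treatment of zeros in the counts of agreement were chosen after the data were seen. The count of 15325 features past the adjusted p fell to 0 in total, higher and lower, both with the features at 0 on both arrays kept (smallest adjusted p 0.11) and in the test without eBayes (smallest adjusted p 0.14). In the former the prior degrees of freedom dropped to 0.74, because the added features have no spread. At an adjusted p of 0.1 the count was 30899, with 15683 higher and 15216 lower. Fold rules without a test gave 4479 features at 1.5-fold (2620 higher, 1859 lower) and 610 at 2-fold (411 higher, 199 lower). Under the ratios as deposited, the common scale, the omission of features at 0 on either array, robust eBayes and the removal of block medians, the count ran from 15196 to 18303, and each of these settings kept at least 14274 of the 15325 features. The share that was higher ran from 49.5% (as deposited) to 54.3%, so which direction held more called features turned with the centring. With the ratio read as P30 over P90, higher and lower are exchanged in all of these counts and below, and this share ran from 45.7% to 50.5%.

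At 1.3-fold in place of 1.5-fold, 13333 features agreed in direction and 457 were opposite, and at 2-fold 610 agreed and 16 were opposite. Read as base 2, the values gave 11 features in the same direction (100% higher, or 0% with the ratio turned) and 0 opposite, and read as natural logs 129 (72.1% higher, or 27.9% turned) and 3 opposite. Either array alone had 8572 to 10240 features at or beyond 1.5-fold. Pearson's r ran from 0.700 to 0.715 over the other settings, and the share of higher features at 1.5-fold from 55.2% to 59.5%, or from 40.5% to 44.8% turned. The 4 named features kept a direction that their selection all but fixed. Neither array can be left out of the moderated test, since 1 array leaves no residual degree of freedom. No paired analysis was possible because each array is already a pair and there is 1 group of arrays. The alternatives per interval, gene, gene list and chromosome were not run.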

Other observations

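Of the 3 patterns below, the agreement of the arrays was a planned result. The remaining patterns, and the tests of causes for all 3, were chosen after the values that show them were seen. Higher and lower at P90 rest on a direction of the ratio that is not stated with the values, and would be exchanged in every paragraph below if it were P30 over P90. Features at exactly 0 on 1 array leaned towards lower values at P90 on the other. The 797 features at exactly 0 on replicate 1 had a median log2 ratio on replicate 2 below that of the 88121 features measured on both arrays, or 1.15-fold lower (difference -0.20, 95% bootstrap interval -0.23 to -0.16). The 1224 features at 0 on replicate 2 had a median on replicate 1 that differed by -0.11 (-0.14 to -0.07), or 1.08-fold. In 100000 permutations each, both gave p = 1e-05, the smallest they can give, with the caution that features of one interval are not independent. The bootstrap redrew only the features at 0, as if independent, with the comparison median fixed. Its intervals therefore hold no error between arrays. At least 1.5-fold lower were 16.3% of the first set, against 4.40% of the features measured on both arrays, and 15.7% of the second set, against 5.10%.

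These features also had a wider spread, with an SD of 0.47 on either array, against 0.37 on replicate 2 and 0.39 on replicate 1 for features measured on both. Against block medians of 12 by 12 features, a share of at least 0.875 of the difference stayed. Smooth position effects on the layout used thus did not account for most of the lean. That layout, 528 rows of 199 features, was inferred from how features at 0 on both arrays recur (autocorrelation 0.024). Position effects finer than a block were not tested. A dye effect cannot be told apart from age here, with 0 arrays in which P30 carried Cy5. What an exact 0 codes for and the brightness of these features are not known here, so causes tied to them were not tested.

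The agreement of the 2 arrays has at least 2 readings that the design leaves confounded. Smooth position effects shared by the arrays would have lowered the correlation when block medians were subtracted, and Pearson's r was 0.704 after the subtraction and 0.700 before. The correlation of neighbouring features was 0.010 on replicate 1 and 0.0067 on replicate 2, taking rows of 199 features. A difference between the ages and a feature-specific dye effect cannot be told apart, because 0 arrays have the dyes swapped. Part of the 15325 calls, of which 8753 are under 1.5-fold, may come from the dyes.

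Features with large increases of the ratio, read as higher at P90, repeated more often than those with large decreases. The mean excess was 26.6 percentage points at 2-fold. It was 25.1 with the ratios as deposited, 23.9 without features at 0 on either array, and 26.4 after removing block medians. Leaving out the zeros argued against them as the whole cause. The centring here removed medians of only -0.021 and -0.0076 (log2) on replicates 1 and 2, so undoing it could change little. Block medians also had little to remove, with neighbouring features correlated at 0.010 and 0.0067 on the inferred layout. Those tests therefore show only that the centring done here and smooth effects on that layout were too small to be the whole cause. Any dye normalization before the values were deposited was not tested. A dye effect, a difference between the ages and scatter specific to an array all stay open. No dye-swapped array, channel intensity or annotation of features was used here to tell them apart. The number of intervals behind the 49 features that were 3-fold higher on both arrays was not determined here.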
